A study of Mus musculus with 9 samples.

How the data were processed

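RNA-seq of 9 E14 clones was analysed, each as 1 sample. Per the labels' protocols, libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the tools were CASAVA 1.8, FastQC, Trimmomatic 0.33 and kallisto 0.43.1, with the builds mm10 and GRCm38. Per the file headers, each deposited table gives for 115270 transcripts a length, an effective length, an estimated count and a TPM value. The estimated counts, which need not be whole, and the TPM values, which are scaled for transcript length and library size by the authors' tool, are both as deposited by the authors. The annotation release behind the transcripts is not given in the sources used here. kallisto divides reads between near-identical transcripts, so that counts of pseudogenes and gene copies can move between them.

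Transcripts were matched by Ensembl identifier to GENCODE M21 (GRCm38), which held 113580 of them (98.53%), and their estimated counts were summed to 35580 genes. The unmatched transcripts held 0.641 to 0.773% of the counts and stayed out of the gene values. Only 19 of the genes were long noncoding, and several imprinted noncoding RNAs are not analysed here. Totals ranged from 10783718 to 14309662 estimated counts per clone, and 3 counts, the limit that a count of 0 allows, stood for 0.211 to 0.28 CPM. These limits, the intervals of folds and those of the unmatched share cover counting error only. The intervals of chromosome steps and of naive and general pluripotency medians come from resampling genes within the libraries. They cover the spread over genes and not a spread between clones. Every pair of clones differed beyond counting noise, in at least 1591 genes, so no deposited table was taken as a copy of another. Separate libraries of 1 clone could also differ beyond counting, so that the clones are distinct rests on the labels.

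The labels used here do not say which clone had which droplet size, so no groups were formed and no clone was treated as a replicate. Values were log2 CPM (edgeR 4.0.16 formula, prior count 2, TMM factors) for 13378 genes with a mean of 1 CPM or more. The range over clones, clones apart by 2 or more, list medians against 10000 random lists matched on level in 20 bins, chromosome medians against 10000 random gene sets, and principal components of 500 genes were described. The designs, 27 gene lists and naming rule were fixed before the data were examined. The rule named the 12 genes and the 12 protein-coding genes with the largest range, up to 3 genes per list with the largest range, list members with a clone apart, up to 3 genes per clone and direction apart by 2 or more, the 10 genes of smallest adjusted p per direction in each score fit, and Pou5f1, Sox2, Nanog, Zfp42, Plin2, Zscan4c, Tert, Terf1, Terf2 and Dnmt3b. Of the genes it named, 2 are not reported here. A list score is the mean over members of log2 CPM scaled over clones.

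Counts were rounded for edgeR quasi-likelihood fits (R 4.3.3) with a list score as covariate, leaving out the list's own members; limma 3.58.1 supplied camera (preset correlation 0.01) and voom, and DESeq2 1.42.0 a second test. Score and genes come from the same libraries, so the counts were set beside 100 permutations and 100 random-list scores. The 10 planned correlations between scores were not computed, because the clones, cut into 3 sets by Spearman's rho, lay in sets of 2, 3 and 4. Steps were tested on simulated data. The counts were drawn gene by gene at a dispersion of 0.01, without sets of similar clones. Of 200 changed genes among 13378, the fit with the naive score recovered 100% at a slope of 1 and 82% at 0.5, with 13 false calls. The simulation therefore says nothing of false calls among genes that vary together over clones. For clones apart, all genes changed by 3 log2 units and none changed by 1.5 were called, with 0 false calls. In that simulation 7 genes outside the 200 had a range of 2 or more. A simulated chromosome step of 0.5 was recovered as 0.47, and the cause of the shortfall was not tested. Alternatives were median-ratio size factors, no filter or 5 CPM, a prior count of 0.5, log2(TPM + 1), the other tests, an unscaled score, 2000 genes for the components and each clone left out. Protein-coding genes alone, the gene mean as reference and 10 other sets of random draws for the chromosome calls were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.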

Results

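Poly(A) RNA from 9 clones of E14, a mouse embryonic stem cell line, was measured by RNA-seq. The clones had been isolated from the bulk line and were grown with serum and leukaemia inhibitory factor on gelatin. The title of the series concerns the exit from naive pluripotency, metabolism and telomere homeostasis, and the clones were picked for lipid droplet size. The labels used here give no clone its droplet size, so all 9 clones stand without a group, each clone is 1 sample, and levels are given clone by clone with no comparison between groups. The summed estimated counts ranged from 10783718 in clone 1 to 14309662 in clone 6, with 13802506 in clone 11 as the median. Between 19181 and 20208 genes per clone had a count. Levels below are CPM, counts scaled by effective library size, ranges are the highest minus the lowest clone on the log2 scale, and intervals of folds are exact 95% intervals that cover counting error only. A count of 0 allowed a level of up to 0.211 to 0.28 CPM, depending on the clone. Genes named outside the rule fixed before the data were examined were chosen after their values were seen: Esrrb, Tfcp2l1, Nr0b1, Zic5, Fasn, Scd1, Me1, Acacb, Elovl6, Fads1, Sqle, Nhp2, Zrsr1, Atf4, Dgat1, Bscl2, Hilpda, Lum, Dcn, Postn, Ddx3y, Eif2s3y, Rhox6, Rhox9 and Lars2, and in the closing section Acly, Acaca, Srebf1, Ctc1, Ten1, Acd, Terf2ip, Tnks and Gapdh.

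The clones differed in many genes. Of 13378 genes with a mean of at least 1 CPM, 1059 (7.92%) had a range of 2 or more log2 units and 4720 (35.28%) a range of 1 or more, with a median range of 0.78. These 1059 included 917 of 12822 protein-coding genes and 142 of 551 pseudogenes. The guanylate-binding protein genes Gbp2 and Gbp2b, which respond to interferon, were highest in clone 11 with 51.2 and 53.8 CPM. Gbp2 had no count in clone 17, so that it was at least 238-fold higher in clone 11, and Gbp2b was 250-fold higher in clone 11 than in clone 17 (interval 85.1 to 1213). Acta2, smooth muscle actin, was at 13 CPM in clone 11 and had no count in clone 17 (at least 60.3-fold). Csf1, a macrophage growth factor, was at 9.78 and 14.8 CPM in clones 10 and 11 and at 1.6 CPM or less in the other 7, with 1 count in clone 8 (208-fold from clone 8 to clone 11, interval 36.8 to 8235). Usp26 on chromosome X was at 0.437, 0.431 and 1.14 CPM in clones 14, 17 and 8 and at 25.4 to 47.8 CPM in the other 6 (111-fold from lowest to highest, interval 50.7 to 303). Fat2 on chromosome 11 was at 0.437, 0.431 and 0.0714 CPM in clones 14, 17 and 8 and reached 14.8 CPM in clone 13 (207-fold, interval 36.8 to 8233). Rps12l1, Rpl10-ps1, Gm9843, Rpl30-ps9, Gm14303, Gm4294 and Rpl15-ps3 were also among the 12 genes with the largest range, but these are pseudogenes or copies that share reads with near-identical genes, and their values are uncertain. Hist1h4m, Gm10131, Gm45837, Gm49369, Gm14288 and CAAA01147332.1, also named by the rule, are histone copies, gene models without an assigned name or sequence outside the chromosomes, and their values are given in no further detail. Counting noise alone was exceeded in 11956 genes (89.37%, chi-square against Poisson sampling, Benjamini-Hochberg adjusted), which says that the libraries differed and nothing of groups. With a minimum of 5 CPM, 355 genes had a range of 2 or more, with log2(TPM + 1) 424, and without a filter 2720.

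Single clones stood 2 or more log2 units from the nearest other clone in 36 genes, 4 times above and 32 times below. Uty, on chromosome Y, was at 3.07 CPM in clone 10 and 47.1 CPM in clone 8, a 15.3-fold difference (interval 11.3 to 21.7). The Y-linked Ddx3y and Eif2s3y were at 6.01 and 8.4 CPM in clone 10 and at no less than 55.9 and 60.3 CPM in any other clone. Alg13, a subunit of the enzyme for the second step of N-glycan assembly, was at 45.3 CPM in clone 11 and 301 to 353 CPM elsewhere (7.79-fold from lowest to highest, interval 7.17 to 8.46). Fam177a had no count in clone 14 and 9.52 CPM in clone 10 (at least 43.5-fold), and Rsc1a1 was at 0.274 CPM in clone 14 and 7.99 CPM in clone 13 (29.1-fold, interval 10.4 to 103). Whether reads of either gene were divided with other transcripts was not tested, so these folds are uncertain. Htr1b, a serotonin receptor gene, was at 0.105 CPM in clone 1 and 2.15 CPM in clone 11 (20.4-fold, interval 3.7 to 905). Of the 36 genes, 15 were pseudogenes. The other genes named by the rule were pseudogenes or gene models without an assigned name: Gm49190 was low in clone 10, Gm20458 in clone 13, AL732309.1 in clone 14, Rps25-ps1, Gm20425 and Gm2810 in clone 17, Gm10093 and Gm2016 in clone 1, AC115631.1, Gm32687 and Gm21962 in clone 4, and B430305J03Rik and Gm2446 in clone 8, while Gm9761 was high in clone 4. Without clone 10 the count was 92, and without clone 11 it was 66.

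**Figure D1:**
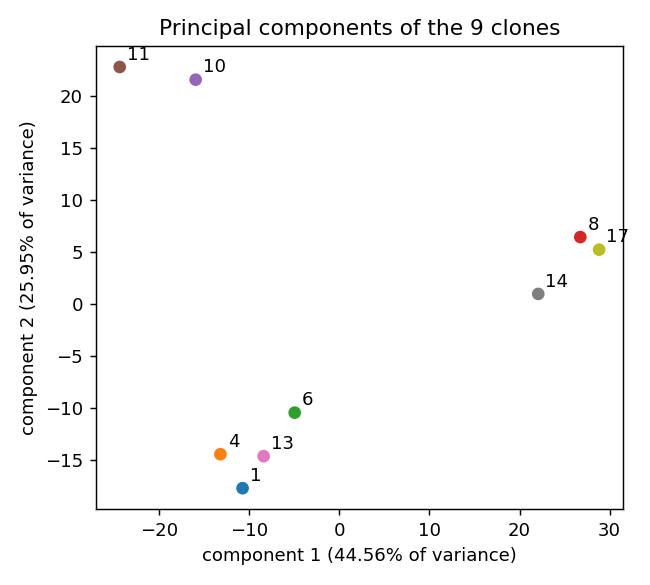
Positions of the 9 clones on the first 2 principal components of the 500 most variable genes (log2 CPM), with the share of variance on each axis. Clones 14, 17 and 8 lie at 22.08 to 28.84 on component 1 and the other clones below 0.

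Naive pluripotency genes varied more between clones than genes of the same level, with a median range of 1.21 over the 14 measured members (percentile 99.99 among 10000 random lists). All 14 passed the filter and 9 had a range of 1 or more. Nanog (chromosome 6, 122707489 to 122714633, GRCm38), a core factor of the naive state, was at 264 and 249 CPM in clones 10 and 11 and at 537 CPM in clone 1, a 2.16-fold range (interval 2.07 to 2.25). It was little higher in clones 14, 17 and 8, at 309, 280 and 326 CPM, and was at 493, 473 and 454 CPM in clones 13, 4 and 6. Esrrb, Tfcp2l1 and Nr0b1 were also lowest in clones 10 and 11, with 382 and 369, 346 and 385, and 69.8 and 69.3 CPM, while clone 17 had 716, 647 and 170 CPM. Dppa3, which protects methylation in the early embryo, followed another order and was at 8.34 CPM in clone 17, 17.4 CPM in clone 8 and 78.9 CPM in clone 4 (9.47-fold from lowest to highest, interval 7.81 to 11.6). Nanog and Dppa3 lie on distal chromosome 6, where the median level of 250 genes was higher in clones 13, 1 and 6, by 0.435, 0.461 and 0.334 log2 units. Clone 4, with Nanog at 473 CPM and the highest Dppa3, lay at -0.051 there. Tbx3 ranged from 25.9 CPM in clone 10 to 82.9 CPM in clone 17, Tcl1 from 38.1 CPM in clone 11 to 136 CPM in clone 8, and Zfp42 from 488 CPM in clone 11 to 873 CPM in clone 4. The list score was -1.09 in clone 10 and -1.27 in clone 11, and 0.17 to 0.42 in the other 7 clones.

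General pluripotency genes varied little, with a median range of 0.57 over 12 members (percentile 53.5, and 8.37 to 67.32 with a clone left out). Pou5f1 was at 851 CPM in clone 11 and 1289 CPM in clone 17, and Sox2 at 236 CPM in clone 11 and 301 CPM in clone 14, folds of 1.51 and 1.28. Dppa5a, L1td1 and Gdf3 had the largest ranges, 1.07, 0.96 and 0.94, and Gdf3 lies on distal chromosome 6.

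Formative and primed genes had a median range of 1.54 over 13 measured members (percentile 99.97). Dnmt3b (chromosome 2, 153649450 to 153687730), the de novo DNA methyltransferase that is more active after the naive state, was at 373 and 460 CPM in clones 10 and 11. It was also at 338 CPM in clone 4, and at 198 to 235 CPM elsewhere. Pou3f1 was at 25.9 and 31.9 CPM in clones 10 and 11 and at 2.95 to 9.99 CPM elsewhere, and Sall2 reached 24.9 and 20.4 CPM in those clones. Lef1, a Wnt effector, went another way and was at 1.32, 0.82 and 1.6 CPM in clones 14, 17 and 8 against 7.32 CPM or more in each other clone. Zic5 was at 8.53, 6.9 and 11 CPM in those 3 clones and at least 20.5 CPM in each of the rest.

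Two-cell-like genes, which mark a rare state resembling the 2-cell embryo, had a median range of 2.34, but only 8 of 29 members passed the filter (percentile 98.6). The Zscan4 family, telomere-linked genes whose members share reads and are given as a family sum, was at 25.3 CPM in clone 11, 18.3 CPM in clone 4, 15.7 CPM in clone 10 and 4 CPM in clone 17, a 6.33-fold range. The Usp17l family summed to 3.65 CPM in clone 11 and 0.448 CPM in clone 17, and the Tdpoz family stayed under 1 CPM. Zscan4f, Zscan4c and Zscan4d had the largest ranges, 3.51, 3.19 and 3.15, with the split between copies uncertain. Zscan4f was at 0.36 CPM in clone 17 and at 1.93 CPM or more in each other clone.

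Lipid droplet and triglyceride genes together varied no more than random lists (median range 0.75 over 26 members, percentile 42.9), with single members apart. Plin2 (chromosome 4, 86648386 to 86670060), the droplet coat protein found in most cells, was at 42.2 and 44.7 CPM in clones 10 and 11 and at 17.3 to 25.3 CPM in the other 7 clones, 2.59-fold from clone 8 to clone 11 (interval 2.23 to 3.01). Dgat2, the last enzyme of triglyceride synthesis, was at 4.52, 3.45 and 3.14 CPM in clones 14, 17 and 8 and 13.6 CPM in clone 1 (4.32-fold, interval 3.05 to 6.2). Fabp5 ranged from 12.4 CPM in clone 17 to 35.1 CPM in clone 10 and Gpat3 from 4.17 CPM in clone 17 to 12.6 CPM in clone 1. Dgat1, Bscl2 and Hilpda had ranges of 0.30, 0.37 and 0.30.

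Fatty acid synthesis genes had a median range of 0.92 (percentile 98.7) and cholesterol synthesis genes 0.83 (percentile 98.8). Fasn, fatty acid synthase, was at 727, 622 and 711 CPM in clones 14, 17 and 8 and at 963 CPM or more in each other clone; it lies on chromosome 11, whose genes were lower in those 3 clones (median deviations of -0.362, -0.39 and -0.405 log2 units). Scd1, which desaturates fatty acids, was at 31.2, 36.5 and 36.4 CPM in clones 14, 17 and 8 and at 57.4 to 69.5 CPM elsewhere, and Fads2 at 20.1, 18.3 and 18.3 CPM there and 41.9 CPM in clone 1. Acss2 was low in clones 14, 17 and 8, at 7.14, 7.9 and 8.57 CPM, and lowest in clone 10, at 6.95 CPM, against 9.08 to 16.8 CPM elsewhere. Other members went differently: Me1 was highest in clones 14, 17 and 8, with 25.3, 30.4 and 28.2 CPM against at most 21.6 CPM elsewhere, and Acacb, Elovl6, Fads1 and Mlxipl were lowest in clones 11, 10, 4 and 1. Of the cholesterol synthesis genes, Insig1, Fdps and Sqle were highest in clone 4, with 113, 222 and 118 CPM, and Sqle reached 118 CPM in clone 1 too. Acss2 and Mlxipl had the largest ranges of the fatty acid list, 1.25 each. With log2(TPM + 1) the percentiles were 85.4 and 88.7.

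Fatty acid oxidation genes did not exceed random lists (median range 0.63, percentile 44.7), though Acadvl was at 24.3, 26.9 and 23.4 CPM in clones 14, 17 and 8 and 74.4 CPM in clone 4, and Cpt1b was at 6.83 and 6.42 CPM in clones 17 and 8 and 1.6 CPM in clone 4. Etfb ranged from 39.1 CPM in clone 8 to 85.2 CPM in clone 6. Glycolysis genes had a median range of 0.78 (percentile 98.9, 57.5 with log2(TPM + 1) and 81.1 without clone 4). Slc16a3, a lactate exporter, was at 80.9, 73.2 and 75.7 CPM in clones 14, 17 and 8 and at 183 to 231 CPM elsewhere, and Pfkfb3 at 10.5, 11.1 and 8.73 CPM there. Acadvl and Slc16a3 lie on chromosome 11, whose genes lay at a median of -0.362, -0.39 and -0.405 log2 units in clones 14, 17 and 8. Both genes were lower there than that shift alone would give. Slc16a3 lay at -1.21, -1.353 and -1.305 log2 units, and the median of Acadvl over the clones was 53.7 CPM. Tpi1, on distal chromosome 6, reached 776, 907 and 657 CPM in clones 13, 1 and 6. Oxidative phosphorylation genes had a median range of 0.55 (percentile 49.4, 16.9 without clone 11 and 3.25 with log2(TPM + 1)). Cox4i1, on chromosome 8, ranged from 338 CPM in clone 11 to 746 CPM in clone 14. Ndufa9, on distal chromosome 6, ranged from 80 CPM in clone 11 to 159 CPM in clone 1, and Cycs from 25.2 CPM in clone 4 to 44 CPM in clone 10.

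**Figure D2:**
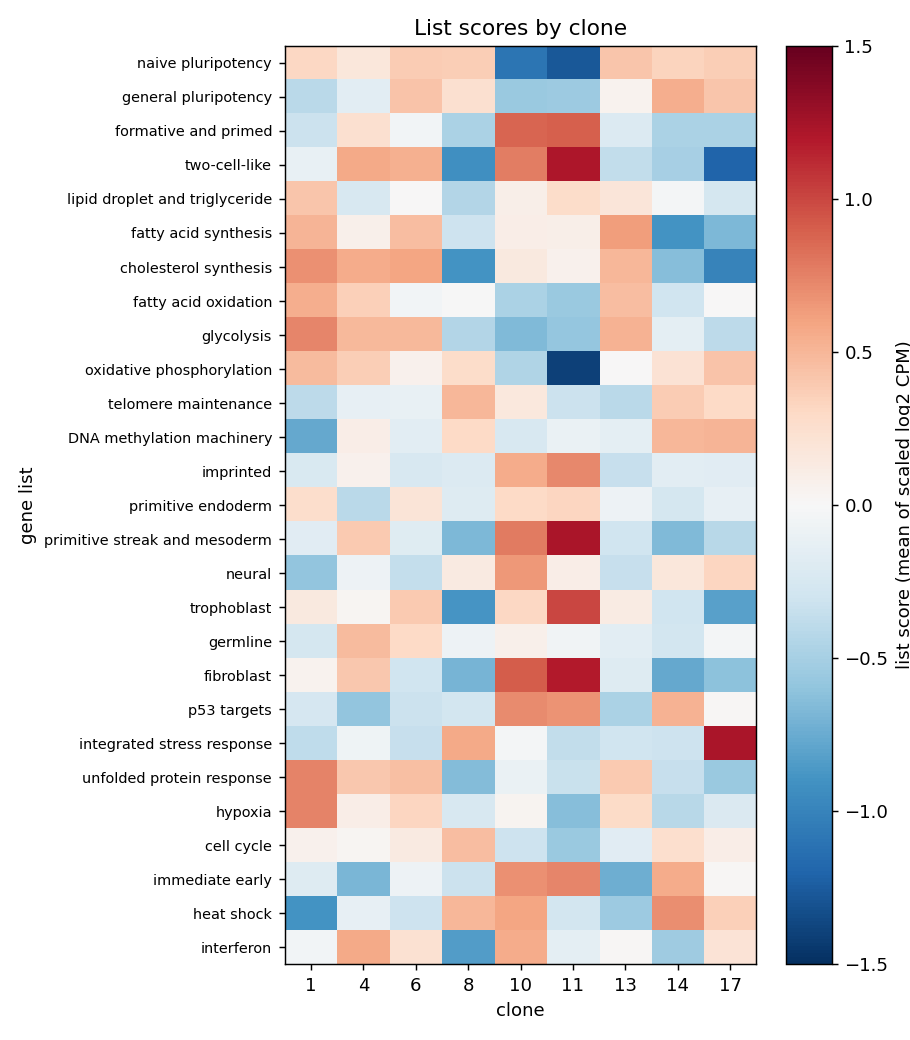
List scores (colour; mean over members of log2 CPM scaled over the 9 clones) for the 27 gene lists (rows) in each clone (columns). The naive pluripotency row is lowest in clones 10 and 11, at -1.09 and -1.27.

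Telomere maintenance genes varied no more than random lists (median range 0.58 over 26 members, percentile 30.3). The percentile was 51.58 without clone 11 and 73.77 with log2(TPM + 1). Tert (chromosome 13, 73626911 to 73649843), the telomerase reverse transcriptase, stayed between 16.2 CPM in clone 11 and 21.5 CPM in clone 8. Terf1, a shelterin subunit, ranged from 55.6 CPM in clone 1 to 125 CPM in clone 14 (2.25-fold, interval 2.05 to 2.48), and Terf2 from 21 CPM in clone 1 to 43 CPM in clone 14 (2.05-fold, interval 1.75 to 2.41). Wrap53 and Nhp2, telomerase components, were lower in clones 14, 17 and 8, with 41.8, 35.9 and 31.7 CPM and 230, 205 and 205 CPM, against 68.2 and 407 CPM in the highest clones. Wrap53 and Nhp2 lie on chromosome 11 and Terf2 on chromosome 8, and the genes of both chromosomes differed in level between clones. Pot1b was at 3.1 CPM in clone 1 and 6.6 CPM in clone 17.

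DNA methylation genes had a median range of 0.81 (percentile 96.6): Tet2 was at 185 CPM in clone 8 and 76.1 CPM in clone 11, and Tet3 at 17.7 CPM in clone 11 and 5.03 CPM in clone 4. Imprinted genes had a median range of 1.68 over 23 members (percentile 100), and 7 of the 31 listed genes had no transcript among those analysed here. Nnat was at 30.5 and 34.1 CPM in clones 10 and 11 and 3.43 CPM in clone 8, Plagl1 at 18.1 CPM in clone 11 and 1.88 CPM in clone 1, and Magel2 at 5.24 CPM in clone 11. Zrsr1 was at 243 CPM in clone 1 and 43.4 CPM in clone 13.

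**Figure D3:**
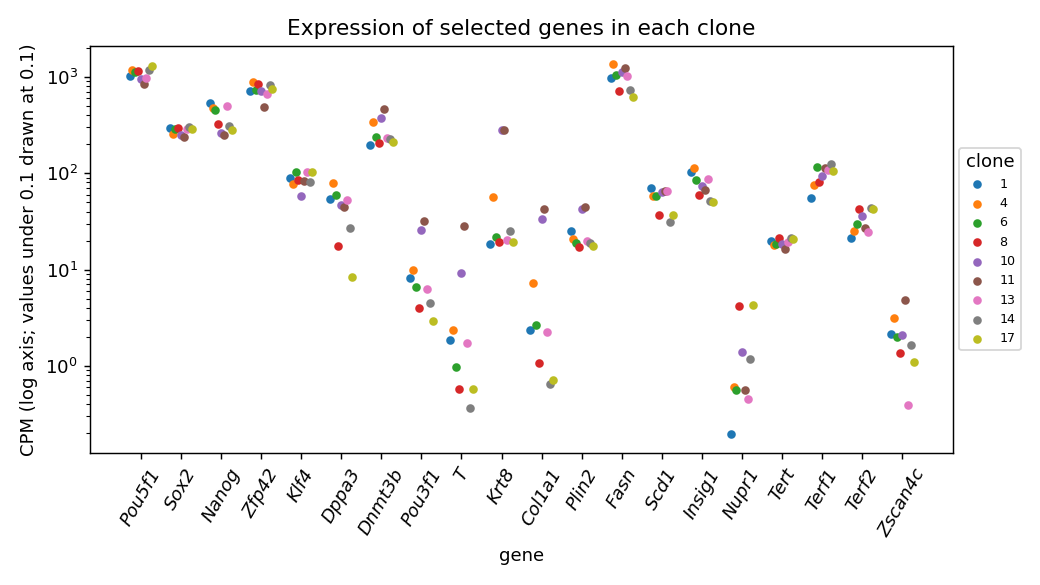
CPM (log axis) of 20 genes in each of the 9 clones, 1 point per clone, with values under 0.1 drawn at 0.1. Krt8 and Col1a1 are highest in clones 10 and 11, while Pou5f1 and Sox2 differ by 1.51-fold and 1.28-fold at most.

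Several genes of differentiated lineages were highest in clones 10 and 11, the clones with the lowest naive scores. Primitive streak and mesoderm genes had a median range of 3.18 over 7 measured members (percentile 100): T, or brachyury, was at 9.2 and 28.2 CPM in clones 10 and 11 and at 2.36 CPM or less elsewhere, Wnt3 at 11.2 and 14 CPM, and Hand1 at 2.97 and 3.14 CPM. Fibroblast genes had a median range of 4.92 (percentile 100). Col1a1 was at 33.4 and 42.5 CPM and Tagln at 36.8 and 54.4 CPM in clones 10 and 11, while Lum, Dcn and Postn reached at most 0.0762, 0.629 and 0.489 CPM in any clone. Trophoblast genes had a median range of 3.19 (percentile 100), with the keratin genes Krt8 at 278 CPM in both clones and Krt18 at 167 and 182 CPM, against at most 56.1 and 38.8 CPM in any other clone. The trophoblast list did not follow these keratins throughout: its score was 1.005 in clone 11 but 0.306 in clone 10, below the 0.393 of clone 6, and Rhox6 and Rhox9, chosen after their values were seen, were highest in clone 1 with 31.8 and 23.2 CPM. Col1a2, of the fibroblast list, was at 8.76 and 7.9 CPM in clones 10 and 11, and with 1 count in clone 17 the difference was 122-fold (interval 21.5 to 4857). Primitive endoderm genes had a median range of 2.03 (percentile 99.9): Col4a2 reached 46.4 and 38.8 CPM in clones 10 and 11, while Hnf4a was low there, at 0.435 and 0.349 CPM, and Amn ranged from 0.5 CPM in clone 8 to 3.32 CPM in clone 1. Neural genes (median range 1.36, percentile 94.2) went both ways, with Nes at 106 and 98.7 CPM in clones 10 and 11, Sox1 at 2.92, 7.11 and 5.28 CPM in clones 14, 17 and 8, and Pax6 from 4.8 CPM in clone 6 to 12.5 CPM in clone 8. The neural percentile ranged from 89.46 without clone 8 to 97.04 without clone 4 and was 77.19 without a filter, 86.64 with a minimum of 5 CPM and 98.76 with log2(TPM + 1). Germline genes had a median range of 1.04 (percentile 52.6), led by Ddx4, Tdrd1 and Dazl. Their percentile was 19.19 to 73.79 with a clone left out, 17.66 without a filter and 9.83 with log2(TPM + 1).

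Integrated stress response genes had a median range of 1.06 (percentile 96.7, and 81.7, 92.9, 93.5 and 94.8 without clone 11, 17, 4 or 8): Nupr1 was at 4.31 and 4.21 CPM, Chac1 at 5.6 and 4 CPM and Atf4 at 202 and 186 CPM in clones 17 and 8, while Atf3 was highest in clone 11 with 6.57 CPM. Unfolded protein response genes had a median range of 0.80 (percentile 92.5, from 56.83 without clone 4 to 95.62 without clone 11, and 78.49 with log2(TPM + 1)). Xbp1, on chromosome 11, ranged from 34.6 CPM in clone 17 to 136 CPM in clone 1, Herpud1 from 8.08 CPM in clone 4 to 20.9 CPM in clone 17, and Dnajb9 from 6.25 CPM in clone 4 to 14.5 CPM in clone 8. Hypoxia genes had a median range of 1.22 (percentile 99.5, and 94 with a minimum of 5 CPM), with Bnip3 at 106 CPM and P4ha2 at 23.8 CPM in clone 1 and Ankrd37 at 7.38 CPM in clone 10. The remaining lists lay below percentile 95 with the settings used throughout: p53 targets (median range 0.71, percentile 85.1, led by Perp, Cdkn1a and Pmaip1), cell cycle (0.50, percentile 22.7, led by Mcm5, Ccnb2 and Top2a), immediate early genes (1.05, percentile 92.3, from 89.4 without clone 17 to 95.52 without clone 11, with 88.94 without a filter and 95.56 with a minimum of 5 CPM, led by Fosb, Klf6 and Ier2), heat shock (0.64, percentile 52.4, led by Hspa1b, Hsph1 and Hspa1a) and interferon (0.90, percentile 68.3, with Bst2 from 12 CPM in clone 1 to 22.5 CPM in clone 11 and Oas1a from 4.47 CPM in clone 14 to 27.4 CPM in clone 4). With a clone left out, the percentile of p53 targets was 55.96 to 87.07 and that of cell cycle genes 9.47 to 34.14. Lars2, annotated as a mitochondrial leucyl-tRNA synthetase gene, was at 71896 CPM in clone 1 and at 2906 to 18738 CPM in the other clones. In clone 1, the library with the lowest total, it held 6.88% of the counts, against 0.3 to 1.89% in the others. Whether these reads come from its mRNA was not tested, so its level is uncertain.

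Whole chromosomes differed in level between clones. Relative to each gene's median over the clones, the 716 chromosome 8 genes lay at a median of 0.265, 0.322, 0.317 and 0.284 log2 units in clones 10, 14, 17 and 8 and at -0.185, -0.208, -0.175 and -0.182 in clones 11, 13, 1 and 4, with clone 6 at -0.01. The 1073 chromosome 11 genes lay at -0.362, -0.39 and -0.405 in clones 14, 17 and 8 and at 0.019 to 0.123 in the other 6 clones. With the threshold of 0.2 and the range of 10000 random gene sets, 10 clone and chromosome pairs were called: chromosome 8 in clones 10, 13, 14, 17 and 8, chromosome 11 in clones 14, 17 and 8, chromosome Y in clone 10 (-0.51, 11 genes) and mitochondrial genes in clone 11 (0.63, 13 genes). With 10 other sets of random draws, chosen after seeing the data, the 8 pairs of chromosomes 8 and 11 and the Y pair were called in all 10, the mitochondrial genes of clone 11 in 9, and those of clone 4 (-0.54, not among the 10 pairs) in 8. Without a filter on low counts 6 pairs were called. Of the genes named here, Zfp42, Col4a2, Sox1, Herpud1, Ankrd37, Mcm5, Ier2, Bst2, Cox4i1, Terf2, Gm10131, Sfrp1, Nkx6-3 and Grtp1 lie on chromosome 8. Fat2, Fasn, Acadvl, Slc16a3, Wrap53, Nhp2, Zrsr1, Wnt3, Hand1, Col1a1, Xbp1, P4ha2, Top2a, Igfbp3, Igf2bp1, Krt19 and Ebf1 lie on chromosome 11. Nanog, Dppa3, Gdf3, Tpi1, Ndufa9, Mitf, Tigar, Gm5884 and Rps25-ps1 lie on distal chromosome 6.

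**Figure D4:**
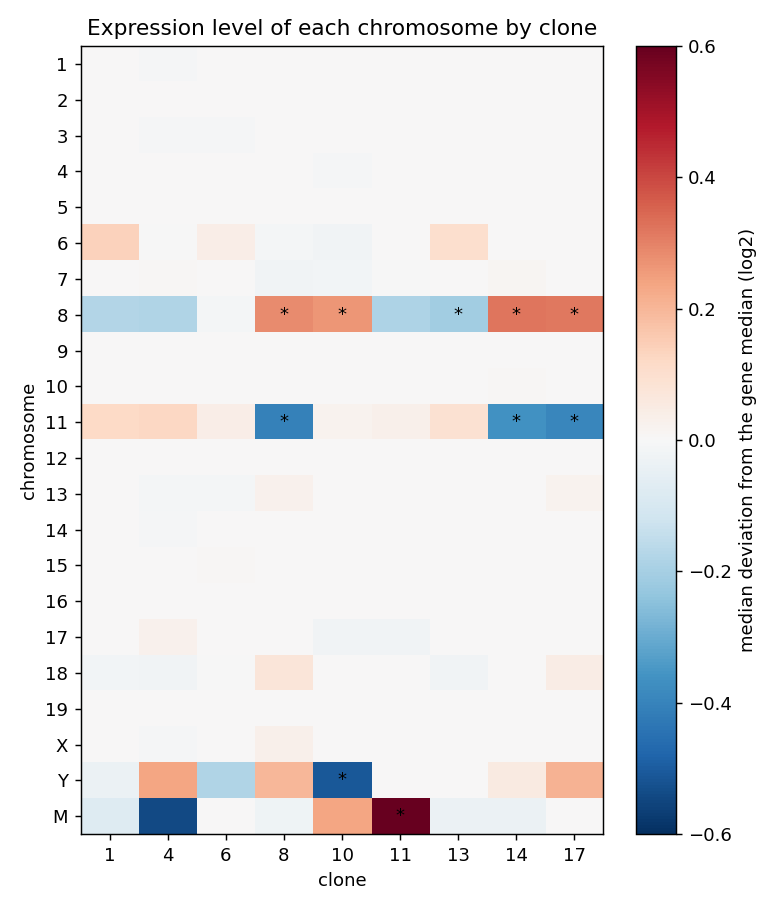
Median log2 deviation of each chromosome's genes from the gene medians over the 9 clones, by clone (columns) and chromosome (rows), with stars on the 10 called pairs and colours ending at 0.6. Chromosome 8 is high in clones 10, 14, 17 and 8, and chromosome 11 low in clones 14, 17 and 8.

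Genes were also fitted against 2 list scores over the 9 clones (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With the naive pluripotency score, 127 genes rose and 443 fell. The smallest adjusted p among genes that fell were those of Tagln, Cald1, Flnc, Kif1a, Anxa3, Igfbp3, Thbs1, Sema6a, Slc25a24 and Piezo2 (edgeR adjusted p from 1.08e-05 to 2.51e-05), with slopes from -1.40 for Cald1 to -2.61 log2 units per score unit for Tagln. Rising genes were led by Manba, Itga9, Mmrn2, Ak7, Nphs1, Epb41l4a, Gm5884, Mitf, Tigar and Ly75 (edgeR adjusted p from 0.000301 to 0.00393), with slopes from 0.48 for Tigar to 3.55 for Gm5884. Fibroblast, formative and primed, imprinted and streak and mesoderm lists fell with the score, each with a camera adjusted p of 0.0172 with an estimated correlation. Of their measured members, 5 of 9, 5 of 13, 5 of 23 and 3 of 7 members fell over all genes, and 5, 7, 7 and 3 adjusted over the list alone. Only with the preset correlation did camera also call trophoblast, neural, p53 target, immediate early and two-cell-like lists downward (adjusted p of 0.0739, 0.115, 0.272, 0.346 and 0.346 with an estimated correlation) and oxidative phosphorylation and glycolysis lists upward (adjusted p of 0.167 and 0.411 with an estimated correlation). With the two-cell-like score, 470 genes rose, led by Acta2, Tnc, Cnn1, Nrk, Esrp1, Pdgfb, Fhl2, Igf2bp1, Gbp2b and Krt19, and 346 fell, led by Pros1, Rapgef3, Sfrp1, Ripply3, Spata31d1b, Nkx6-3, Ebf1, Tet2, Dact2 and Grtp1 (edgeR adjusted p from 0.00599 to 0.00648). No list passed camera with an estimated correlation for that score. Only with the preset correlation did it call trophoblast, fibroblast, formative and primed, streak and mesoderm, imprinted and cholesterol synthesis lists upward (adjusted p of 0.0589, 0.0848, 0.0848, 0.0908, 0.324 and 0.581 with an estimated correlation) and naive pluripotency and integrated stress response lists downward (adjusted p of 0.324 and 0.581 with an estimated correlation).

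These fits rest on few clones. Of 100 scores from random lists of the same size and level, 26 gave as many genes as the naive score's 570 and 10 as many as the two-cell-like score's 816, while none of 100 permutations of the scores did, with at most 496 and 583 genes. Without clone 10 or 11 the naive count was 191 or 122. The two-cell-like count was 340, 338, 59, 168 and 1287 without clone 10, 14, 17, 8 and 13, and without clone 11 it was 0 by edgeR with 2545 genes at an unadjusted p under 0.05; no other tool was run without that clone. The 10 planned correlations between list scores are not given, because the clones, when cut into sets by Spearman's rho, lay in sets of fewer than 6. The fits above use the same clones and share this limit.

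**Figure D5:**
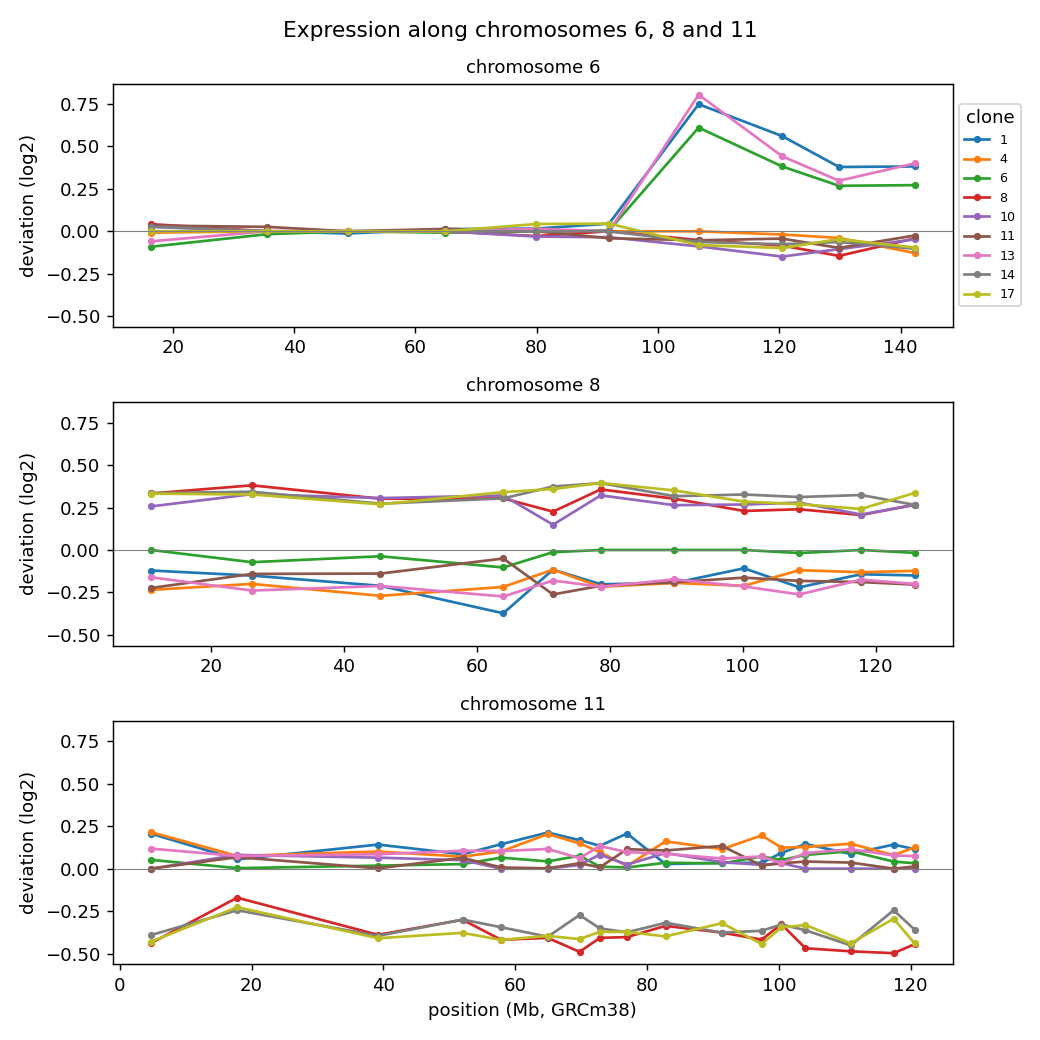
Median log2 deviation in windows of about 60 genes along chromosomes 6, 8 and 11 (position in Mb, GRCm38), 1 line per clone. In each window of chromosome 8 clones 10, 14, 17 and 8 lie above the other 5, and in each window of chromosome 11 clones 14, 17 and 8 lie below the other 6, while the distal part of chromosome 6 is raised in clones 13, 1 and 6.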

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

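Transcripts without a gene in the annotation, which enter the totals per clone but no gene value above, held 0.773% of the estimated counts in clone 14 (Wilson 95% interval 0.768 to 0.777), the highest share, and 0.641% in clone 1 (0.636 to 0.646), the lowest. There were 1690 such transcripts, and their share lay far above the limit that a count of 0 allows in each of the 9 clones. No explanation was tested for this share.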

How the results depend on the processing

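Genes with a range of 2 or more numbered 1059, and 887 to 1031 with a clone left out; without a filter on low counts there were 2720 of 24872 genes, with a minimum of 5 CPM 355, and with log2(TPM + 1) 424, where fewer or more low genes enter or the added 1 shrinks low genes. Clones apart numbered 36, and 69, 16 and 17 in the same order, 31 to 92 with a clone left out (92 without clone 10, 66 without clone 11), and 21 in protein-coding genes, a setting chosen after seeing the data. Chromosome calls numbered 10, 6 without a filter and 7 to 13 with a clone left out; relative to the gene mean, also chosen after seeing the data, there were 15, and with 10 other sets of random draws the mitochondrial calls came and went. The share of component 1 was 44.56% and lay at 39.15 to 51.24% with a clone left out. Of 11 alternative settings for the components, 2 were rated the same as the main one and 9 were not, so the layout is not taken as stable. Of 27 lists, 14 lay at percentile 95 or more and 12 to 16 did under the alternatives; 19 of 376 single percentiles crossed 95, in 8 lists, and the cause was not tested. Genes tracking the naive score numbered 570, 1026 with DESeq2, and 122 to 626 with a clone left out (191 without clone 10, 122 without clone 11). Genes tracking the two-cell-like score numbered 816, 1667 with DESeq2, 250 without a filter, and 0 to 1287 with a clone left out: 340 without clone 10, 0 without clone 11, 1287 without clone 13, 338 without clone 14, 59 without clone 17 and 168 without clone 8; the cause was not tested. The alternatives planned for the 10 correlations were not run. Depth limits genes near 1 CPM, where 3 counts stand for 0.211 to 0.28 CPM.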

Other observations

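The tests of windows, copy number, chromosome 11 content, dilution and a small share of differentiated cells were chosen after the results were seen, and the match on GC content and length before. Over the 13378 genes the clones were cut into 3 sets by Spearman's rho, with the number of sets set to 3 and not derived by the method. Spearman's rho, across genes, which are not independent replicates, was 0.9898 between clones 10 and 11, at least 0.9842 among clones 13, 1, 4 and 6, and at least 0.991 among clones 14, 17 and 8, while the highest rho of a clone to one outside its set was 0.9796. On component 1 clones 14, 17 and 8 lay at 22.08, 28.84 and 26.75, clones 10 and 11 at -15.96 and -24.39, and clones 13, 1, 4 and 6 at -8.41, -10.75, -13.21 and -4.96. On component 2 clones 10 and 11 lay at 21.62 and 22.84 and clones 13, 1, 4 and 6 at -14.62, -17.7, -14.43 and -10.43. The labels used here give no reason for these sets.

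Distal chromosome 6 (97183670 to 149563329, GRCm38), a part chosen after its values were seen, lay at 0.435, 0.461 and 0.334 log2 units in clones 13, 1 and 6 and between -0.101 and -0.051 in the other 6 clones over 250 genes, while the proximal 378 genes lay between 0 and 0.012 in every clone. The rise was uneven along this part. In clones 13, 1 and 6 the window from 97183670 to 116193486 lay at 0.805, 0.749 and 0.611. The window from 124739189 to 134925513 lay at 0.298, 0.379 and 0.268. Nanog, Dppa3, Gdf3, Gapdh, Tpi1, Ndufa9, Mitf, Tigar, Gm5884 and Rps25-ps1 are among its genes. Chromosomes 8 and 11 and distal chromosome 6 held 2039 genes, of which 183 (8.97%) had a range of 2 or more, against 876 of 11339 (7.73%) elsewhere, with median ranges of 0.976 and 0.734.

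Chromosome 8 and 11 genes differed in level between clones. Genes on other chromosomes matched on GC content, transcript length and level deviated by at most 0.01 log2 units, which argues against GC content or transcript length bias. In the called clones 100% of 106 windows of about 60 genes had the sign of their chromosome, so the shift ran along the chromosome rather than a part of it. A few genes could hardly move a median over 716 or 1073 genes, so the calls had largely settled that question beforehand. The 106 count each window once per called clone, and clones 14, 17 and 8 are similar to each other. A difference in chromosome copy number may account for the pattern: the highest minus the lowest clone was 0.575 log2 units on chromosome 8 (clone 14 minus clone 13, interval 0.551 to 0.604) and 0.559 on chromosome 11 (clone 4 minus clone 8, interval 0.529 to 0.594), the same way in 11 of 11 and 17 of 17 windows, and the intervals of these extreme pairs include the log2 ratio of 3 copies to 2. The intervals also included it for clone 14 above clones 11, 1 and 4 on chromosome 8 (0.576, 0.567 and 0.56) and clone 1 above clone 8 on chromosome 11 (0.565). Further steps fell short of that ratio. They were 0.51, 0.544 and 0.52 for clones 10, 17 and 8 above clone 13 on chromosome 8. On chromosome 11 they were 0.463, 0.51, 0.541 and 0.494 for clones 10, 11, 13 and 6 above clone 8 (highest upper bound of these steps 0.578). Clone 6 lay only 0.164 above clone 13 on chromosome 8 (interval 0.151 to 0.175). Copy number is therefore a hypothesis from RNA alone, with no DNA analysed here.

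By their medians, cholesterol synthesis genes and the chromosome 11 members of the fatty acid synthesis list were lower in clones 14, 17 and 8, the clones with low chromosome 11. No cholesterol synthesis gene of the list lies on chromosome 11, and the 21 outside chromosome 8 lay at -0.275, -0.365 and -0.314 log2 units in these clones, below the 95% range of random genes in all 3 (its lowest bound was -0.082), so their own position on chromosome 11 is no explanation and an indirect effect of chromosome 11 content stays open. For fatty acid synthesis the 4 chromosome 11 members, Fasn, Acly, Acaca and Srebf1, lay at -0.457, -0.551 and -0.414, and the 10 on other chromosomes at -0.241, -0.028 and -0.061, outside the range of random genes in clone 14 only, so chromosome 11 content alone stays open there. Telomere genes on chromosome 11 (Nhp2, Wrap53, Ctc1 and Ten1) lay at -0.34, -0.563 and -0.559 in these clones, those on chromosome 8 (Terf2, Acd, Terf2ip and Tnks) at 0.328, 0.318 and 0.242, and the other 18 at 0.101, 0.056 and 0.14. No other explanation was tested.

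Naive genes were lower in clones 10 and 11, and mesoderm and fibroblast genes and the keratin genes Krt8 and Krt18, taken from the trophoblast list after their values were seen, were higher. Dilution by cells without pluripotency transcripts would lower naive and general pluripotency genes alike. The naive minus the general median was -0.304 log2 units in clone 10 (interval -0.737 to -0.088) and -0.53 in clone 11 (interval -0.765 to -0.126), which argues against dilution as the whole cause for the naive genes. These intervals resample genes within 1 library each. Clones 10 and 11 were also picked for their low naive genes, which favours a gap below 0, so the evidence is limited. For the mesoderm, fibroblast and keratin genes a small share of differentiated cells stays open, since general pluripotency genes lay at -0.101 in clone 10 (interval -0.185 to -0.064), below 0 as such a share would give, and at -0.069 in clone 11 (interval -0.332 to 0.035), which includes 0. Of the 16 fibroblast genes 7 were below the filter; Tagln and Col1a1 reached 54.4 and 42.5 CPM in clone 11, and Lum, Dcn and Postn at most 0.0762, 0.629 and 0.489 CPM in any clone. No explanation other than these mixtures was tested, because the labels used here put these clones in no group.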
